A study of Mus musculus with 12 samples.

How the data were processed

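The series holds 12 libraries, all described by the labels as made from infralimbic prefrontal cortex of fear-conditioned male mice taken directly after extinction training (EXT) or a retention control exposure (RC). Peak lists of 5 ATAC-seq libraries were analysed, 3 RC and 2 EXT. The labels state that tissue of 5 mice was pooled per library, so a replicate is a pool of animals. EXT replicate 3 and the 6 lncRNA capture libraries (3 per group, 4 mice pooled in each) were not analysed here. Groups and replicate numbers were taken from the sample titles. The file of EXT replicate 2 carries another number in its name than its title, and the title was followed.

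Per the submitters' processing notes, reads were assigned to the mouse build mm10, and the tools named are cutadapt 1.17, HISAT2 2.1.0, BWA 0.7.17, SAMtools 1.8, StringTie 2.1.4, bedtools 2.27.1 and MACS2 2.2.4. Those notes cover both library types, and which aligner served the ATAC-seq reads is not given in the sources used here. Per the file headers, the authors called peaks in each library separately with MACS 2.2.4, with no control library, no model building, tags shifted by -75 bp and extended to 150 bp so that they centre on the cut site, all duplicates kept, paired-end mode off and a q-value cutoff of 0.05. Duplicate tags kept in this way can raise peaks that rest on few molecules. The deposited pileup column is a coverage signal, the number of extended tags at the peak summit; the headers set the option to save signal scaled to the library total, but the values are whole numbers and were therefore read as unscaled tags. Fold enrichment is the authors' ratio of that pileup to the local background of the same library, per the file headers. The deposited −log10 p and −log10 q values come from the same background. Folds, pileups and −log10 values belong to their own list and were used only to describe or rank peaks within it. Total tags per library, 57.7 M to 73.8 M, and tag sizes, 120 to 143 bp, were read from the file headers. MACS takes the tag size from a small number of tags at the start of its input, so it is a rough figure. No read counts per region were used, so precision is given by the spread between libraries and, for shares of genes in a single library, by exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

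Of the 5 lists, 2 stop within chromosome 1 in the middle of a line, as held here. That incomplete line was dropped in each. Peaks and genes were then compared over 3 extents: chromosome 1 up to position 37624379 (all 5 lists), chromosome 1 up to position 166286196 (all lists but RC replicate 2) and the whole genome (RC replicate 3 and both EXT lists). All peaks lay on chromosomes 1 to 19, X and Y.

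Gene positions were taken from a RefSeq gene table of the assembly GRCm38.p6, the same build as mm10, with 21887 protein-coding and 12727 lncRNA genes. The planned windows around transcription starts were replaced, because strand was not used here: a gene counted as having an end peak when a peak overlapped, by at least 1 bp, the 1 kb either side of its lower or upper end. Such windows take in the 3′ end as well as the 5′ end and miss promoters inside the annotated span. The number of log2 peaks, the share of peaks at gene ends, the shares of protein-coding and lncRNA genes with an end peak, and the mean Jaccard index within less between groups were compared by two-sided exact permutation over the 10 ways to part 5 libraries into 3 and 2, which cannot give p under 0.1. Standard errors of Jaccard indices came from 1000 bootstrap draws of 1 Mb bins. Shares of 14 gene lists (264 genes, all matched to the table by symbol or synonym) were set beside 10000 random lists of the same size from the same class of genes, as a description of each library.

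The groups, the tests, the gene lists and most alternatives were fixed before the data were examined. So was the rule for named genes: all immediate early and 14-3-3 genes; the 10 protein-coding and 10 lncRNA genes with the highest mean within-list rank of their best end peak among those in both EXT lists and no RC list that reached them, leaving out protein-coding genes named only by an identifier; up to 10 genes in at least 2 RC lists and no EXT list; the 5 highest-ranked peaks of each library; and, of every other list, the 2 members in most and the 2 in fewest libraries. A few of the genes that this rule selects are not reported here. Gene names and positions follow the table, and positions are 1-based. Alternatives were a stricter list (−log10 q of at least 5), lists of equal length, leaving out each library, leaving out lists shorter than 10% of the longest, pairing by replicate number, windows of 500 bp and 2 kb, the summit in place of the peak, and other measures of overlap. Chosen after the lists were seen were the shared part of chromosome 1 that all tests use, the windows at gene ends, and the limit of the naming rule to lists that reach a gene. Alternatives added then were the 2 wider extents, the lists as they stand, whole gene spans, and subsets by tag size. The counting of genes was tested on simulated lists: of 200 genes on chromosome 1 given a peak in the simulated EXT lists alone, 200 were recovered among 2051 genes, and 0 others were called. All simulated lists shared their other peaks, up to a small shift, and none of those lay near the 200 genes. The step thus checks the counting alone, and not how often lists that differ as the real ones do would give such genes. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9.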

Results

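Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in activated neurons of the infralimbic prefrontal cortex of adult male C57BL/6 mice. The cells were sorted for the neuronal protein NeuN together with Arc, the product of an immediate early gene that neurons switch on when they are active. All mice had received 3 pairings of a tone with a foot shock. One day later the extinction (EXT) mice heard 60 tones in a second context, and the retention control (RC) mice spent the same time there with no tones. Tissue from 5 mice was pooled for each library, and 50000 cells were used. Peak lists of 3 RC and 2 EXT libraries were analysed. These libraries held 69.1 M, 68.9 M and 73.8 M tags for RC replicates 1, 2 and 3, and 65.0 M and 57.7 M for EXT replicates 1 and 2.

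The lists did not cover the same part of the genome. Those of RC replicate 3, EXT replicate 1 and EXT replicate 2 ran from chromosome 1 to chromosome Y and held 97961, 80735 and 123375 peaks. As held here, the list of RC replicate 1 ended on chromosome 1 at position 166286196 after 6451 complete peaks, and that of RC replicate 2 ended on the same chromosome at position 37624379 after 1248. Comparisons between the groups were therefore made on chromosome 1 up to position 37624379, the part that all 5 lists reached. Whole-genome values came from the 3 complete lists, with a single RC library and hence no test between groups. The tests, gene lists and rules for naming genes were set before the data were examined, but the shared part of chromosome 1, the windows at gene ends and the limit of the naming rule to lists that reach a gene were chosen once the files were seen. The p-values measure the spread between libraries that are each a pool of 5 mice.

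The number of accessible regions did not separate extinction training from the control exposure. On the shared part of chromosome 1 there were 1104 ± 183 peaks (SD, n = 3) in the RC libraries and 981 ± 243 peaks (SD, n = 2) in the EXT libraries. Single libraries ranged from 809 peaks in EXT replicate 1 to 1248 in RC replicate 2, and EXT replicate 2 held 1153. The difference of the mean log2 numbers was -0.18, less than the spread within either group (two-sided exact permutation p = 0.5, where 3 libraries against 2 allow no p under 0.1). It was 0.076 without EXT replicate 1 and 0.105 without the RC replicate 1 and 2 lists, so the sign depended on which libraries were kept. Over the whole genome, peaks covered 27.9 Mb in RC replicate 3, 22.3 Mb in EXT replicate 1 and 39.1 Mb in EXT replicate 2.

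**Figure D1:**
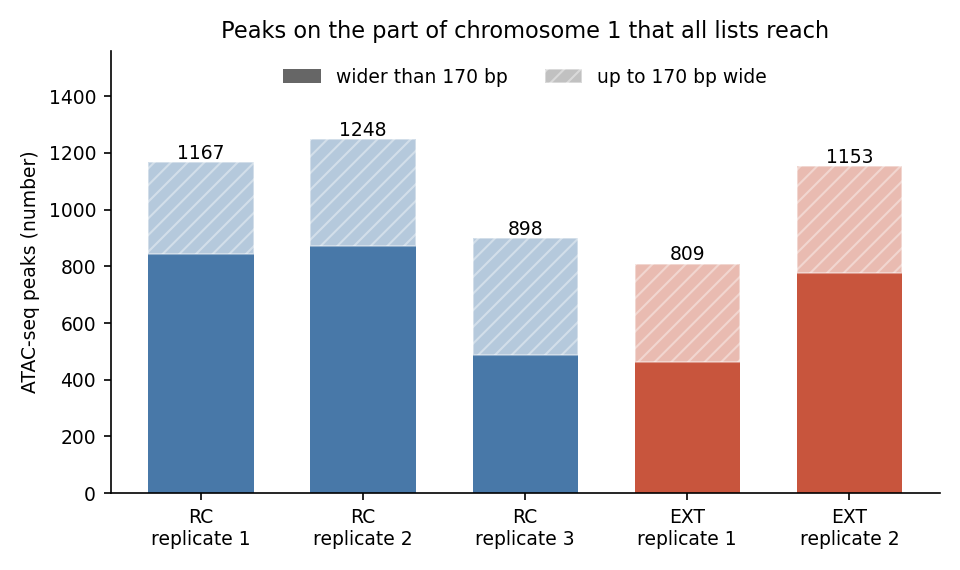
Number of ATAC-seq peaks per library on the part of chromosome 1 that all 5 lists reach, RC libraries in blue and EXT libraries in red, with peaks up to 170 bp wide hatched on top of wider ones. The 809 and 898 peaks of EXT replicate 1 and RC replicate 3 lie below the 1153 to 1248 of the other libraries, and 43.0% and 45.9% of them are narrow.

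Most peaks lay inside genes, away from their ends. The share of the genome in each class was not measured, so the shares of peaks show neither enrichment nor depletion. In RC replicate 3, EXT replicate 1 and EXT replicate 2, 18.6%, 20.7% and 17.1% of peaks in the whole genome touched a window of 1 kb either side of a gene end, 55.3%, 53.7% and 55.9% lay elsewhere within a gene, and 26.1%, 25.6% and 27.1% lay outside genes. On the shared part of chromosome 1 the share at gene ends was 13.5% ± 1.44 (SD, n = 3) in RC and 14.7% ± 2.85 (SD, n = 2) in EXT libraries, a difference of 1.174 percentage points (two-sided exact permutation p = 0.6). The difference was -0.839 percentage points without EXT replicate 1.

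Protein-coding genes carried an accessible end more often than long noncoding RNA (lncRNA) genes, the class that the study set out to capture. Of 21887 protein-coding genes, 56.1% had a peak at an end in RC replicate 3 (exact 95% binomial interval 55.4 to 56.7%), 53.3% in EXT replicate 1 (52.7 to 54.0%) and 61.1% in EXT replicate 2 (60.5 to 61.8%). Of 12727 lncRNA genes the shares were 31.5% (30.7 to 32.3%), 28.0% (27.2 to 28.8%) and 38.3% (37.5 to 39.2%). The EXT libraries lay on either side of the RC library for both classes. For the 157 protein-coding genes of the shared part of chromosome 1, the mean was 55.8% ± 3.14 (SD, n = 3) in RC and 55.1% ± 2.26 (SD, n = 2) in EXT libraries, and for its 116 lncRNA genes 29.0% ± 3.59 (SD, n = 3) and 28.0% ± 4.26 (SD, n = 2). Both differences, -0.743 and -1.01 percentage points, were smaller than the spread within groups (two-sided exact permutation p = 0.8 for each). They turned to 0.849 and 2.01 percentage points without EXT replicate 1, and to 0.319 and 0.431 without RC replicate 2.

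No gene on the shared part of chromosome 1 had an accessible end in both EXT libraries and in none of the 3 RC libraries. Of the 273 genes there, 96 had an end peak in all 5 lists and 134 in none. The other pairs of libraries had between 0 and 2 genes of their own. On the longer part of chromosome 1, which 4 lists reach, the EXT pair had 8 of 1597 genes to itself and RC replicate 1 with EXT replicate 2 had 67, while the other pairs had 3 to 10. Over the whole genome, 756 of 34614 genes had an end peak in both EXT lists and not in RC replicate 3, while 492 had 1 in RC replicate 3 and in neither EXT list. RC replicate 3 and EXT replicate 2 shared 1761 genes that EXT replicate 1 lacked. RC replicate 3 and EXT replicate 1 shared 506 that EXT replicate 2 lacked, and 13520 genes had an end peak in all 3 lists. The list of RC replicate 1 reached 40 of the 756 genes and held an end peak for 32 of them, or 80.0% (exact 95% binomial interval 64.4 to 90.9%). That interval treats the genes as separate, although windows of neighbours such as Msc and Gm9947 overlap. The count of 756 thus rests on RC replicate 3 alone for most of the genome.

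Among protein-coding genes with an end peak in both EXT lists and in no RC list that reached them, those ranked highest included Axl, a receptor tyrosine kinase, Dync2h1, a motor protein of cilia, Cep135, a centriole protein, Slc16a1, a lactate and pyruvate transporter, and Dlgap3, a scaffold protein of excitatory synapses. The Cep135 peaks, at chromosome 5 positions 76588886 to 76589045 in EXT replicate 1 and 76588536 to 76589246 in EXT replicate 2, lay at the lower end of the gene (76588653 to 76646466), with fold enrichments over local background of 6.85 and 9.82. At Slc16a1 (chromosome 3, 104638664 to 104658462) the peaks spanned positions 104638494 to 104638714 and 104638442 to 104639123, with folds of 4.46 and 7.93. The Dlgap3 peaks lay at opposite ends of the gene in the 2 EXT lists, so they were not the same region. For Tpbg, a membrane glycoprotein, both lists gave the same 160 bp peak on chromosome 9, positions 85843229 to 85843388. Ctu2 and Rnf166, neighbours on chromosome 8, were named by the same peaks, which did not overlap between the EXT lists. In EXT replicate 1 their peak and that of Cep135 were also 160 bp wide, and that of Dlgap3 was 150 bp wide. These were the most common widths in each complete list. The EXT peaks of Axl, Dync2h1, Klhl42 and Cfap206 overlapped peaks of RC replicate 3 that did not reach the window, so these regions were open in that library as well. In the whole set of 756 genes, the best peak of at least 1 EXT list overlapped an RC replicate 3 peak for 41, and neither did for 715.

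The 10 lncRNA genes chosen in the same way were Gm3434, Gm17552, Gm31379, Gm35343, Gm33502, Gm46218, 1700010G06Rik, Gm35037, Gm31564 and Gm51499. Peaks of Gm17552 and Gm35037 also overlapped RC replicate 3 peaks, and those of Gm3434 and 1700010G06Rik did not overlap between the EXT lists. The EXT replicate 1 peaks of Gm3434 and Gm46218 had the common width of 160 bp. Peaks of Gm31379 lay at its lower end (chromosome 4, 24851061 to 24879286), at 24850881 to 24851310 with a fold of 4.76 in EXT replicate 1 and at 24850786 to 24851285 with a fold of 7.38 in EXT replicate 2. Gm35343 (chromosome 17, 15044141 to 15056193) had peaks at its upper end with folds of 4.51 and 10.4. All 20 genes lay on chromosomes that a single RC list covered.

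The opposite pattern, an end peak in at least 2 RC lists and in no EXT list, held for 9 genes. All lay on chromosome 1, the only one that 2 or more RC lists reach, and on that part 7 genes had an end peak in both EXT lists and no RC list that reached them. They included the protein-coding genes Sema4c, Kcnq5, Teddm1b and Rnf152 and the lncRNA genes Gm34596, Gm39627, Gm41981 and Gm16150. Kcnq5, a voltage-gated potassium channel subunit (21398399 to 21962650), was the only gene with an end peak in all 3 RC lists and neither EXT list, with folds of 2.94, 3.65 and 2.38 in RC replicates 1, 2 and 3. Only the 273 genes of the shared part could show this, since the RC replicate 2 list reaches no further. Among these, 7 genes were missing from RC replicate 3 and EXT replicate 1 alone, 2 from RC replicate 3 and EXT replicate 2 alone, and 0 or 1 from each other pair. Of the 1597 genes that 4 lists reach, 67 were missing from RC replicate 3 and EXT replicate 1 alone and 7 from the EXT pair alone. The Kcnq5 peaks were weak, at the 33.5th, 50.0th and 7.1st percentile of their own lists, and that of RC replicate 1 lay apart from those of the other RC libraries. The strong peaks near Sema4c, a semaphorin, with folds of 11.6 and 14.4 in RC replicates 1 and 2, overlapped peaks in both EXT lists that did not reach the window, and the Gm16150 peaks of RC replicates 1 and 3 overlapped a peak in 1 EXT list.

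Libraries of the same group did not resemble each other more than libraries of different groups. RC replicates 1 and 2 and EXT replicate 2 shared the most: the Jaccard index, the number of bases in both peak sets over the number in either, was 0.489 between the RC pair, and 0.466 and 0.484 between each of them and EXT replicate 2. RC replicate 3 and EXT replicate 1 reached 0.373. The remaining 6 pairs lay between 0.255 and 0.344, the EXT pair at 0.291 among them. The mean over the 4 pairs within groups less that over the 6 pairs between groups was -0.0106 (two-sided exact permutation p = 0.8), and 0.0769 without EXT replicate 2 and 0.0213 without RC replicate 3. In the 3 complete lists the EXT pair, at 0.313, again overlapped less than RC replicate 3 did with EXT replicate 1 (0.405) or EXT replicate 2 (0.390).

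**Figure D2:**
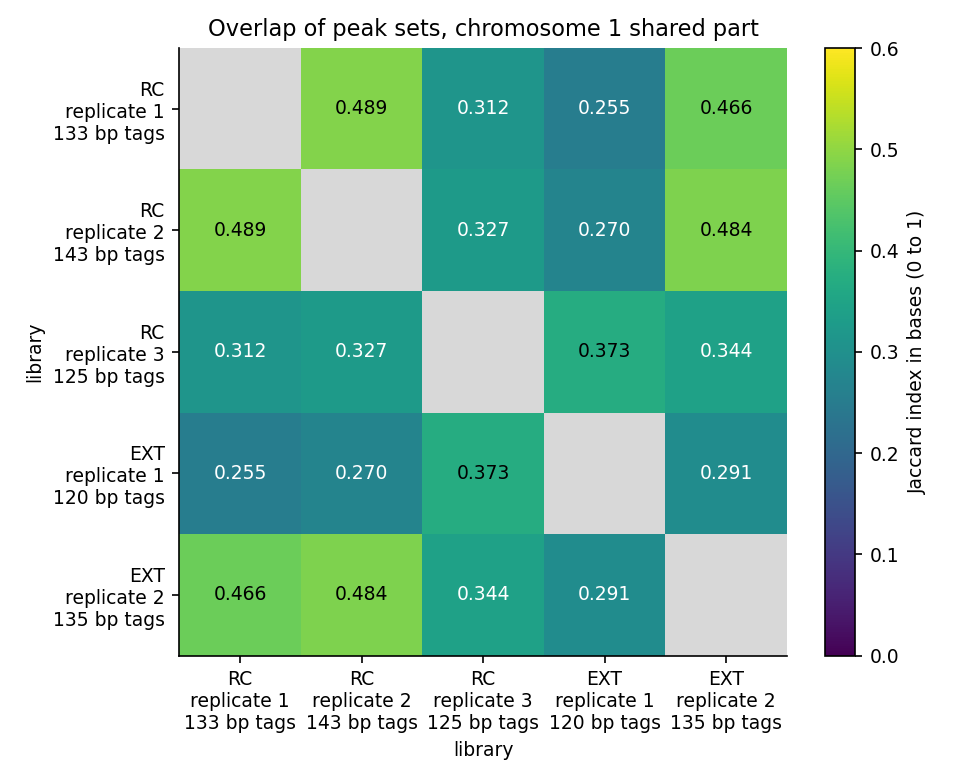
Jaccard index in bases (0 to 1) for each pair of the 5 libraries on the shared part of chromosome 1, with the tag size that the peak caller recorded for each library. RC replicates 1 and 2 and EXT replicate 2 form a block of 0.466 to 0.489, above the 0.255 to 0.373 of all other pairs.

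Immediate early genes, the class to which the sorting marker belongs, were accessible at their ends in nearly all cases and in both groups. Of 28 genes, 26 had an end peak in RC replicate 3, 22 in EXT replicate 1 and 26 in EXT replicate 2. These shares of 92.9%, 78.6% and 92.9% lay at the 99.7th percentile or above among 10000 random lists of 28 protein-coding genes. Housekeeping genes lay at the 99.8th percentile or above in the same lists, so this standing is not particular to immediate early genes. Arc, Fos, Fosb, Junb, Egr1, Nr4a3, Btg2, Homer1 and 14 other genes had an end peak in all 3 lists. Npas4, Nr4a1, Bdnf and Ccn1 had 1 in RC replicate 3 and EXT replicate 2 and not in EXT replicate 1, and Egr2 and Nr4a2 in none. At Npas4 the RC replicate 3 peak (chromosome 19, 5001660 to 5002462) overlapped peaks of both EXT lists, so this region was open in EXT replicate 1 too. The share less that of all protein-coding genes was 36.8 percentage points in RC replicate 3 and 25.2 and 31.7 in EXT replicates 1 and 2, a difference between groups of -8.33 with no test. It was 0.269 with windows of 500 bp, where the order of the groups turned.

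Around Arc (chromosome 15, 74669081 to 74672570, mm10) the 3 complete lists placed a peak at the upper end of the gene. It ran from 74672290 to 74672831 in RC replicate 3 with a fold of 2.54, from 74672667 to 74672836 in EXT replicate 1 with a fold of 2.25, and from 74672539 to 74672872 in EXT replicate 2 with a fold of 4.01. Within its own list the peak stood at the 65.5th, 43.2nd and 91.8th percentile. The 10 kb either side of Arc and the gene itself held 7, 6 and 9 peaks. Nr4a2, an orphan nuclear receptor gene (chromosome 2, 57106830 to 57124003), had no peak within 1 kb of an annotated end in any complete list, although each list had a peak inside the gene. It ran from 57114971 to 57115445 in RC replicate 3 (fold 2.74), from 57114907 to 57115473 in EXT replicate 1 (fold 3.63) and from 57114756 to 57115278 in EXT replicate 2 (fold 6.47). Both EXT lists also held a peak with the same bounds, 57108195 to 57108344, which RC replicate 3 lacked, with folds of 4.02 and 4.09. It was 150 bp wide, the length to which tags were extended, a common width in every list. Within the lists of EXT replicates 1 and 2 it stood at the 45.7th and 31.9th percentile. That peak was singled out after its values were seen.

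**Figure D3:**
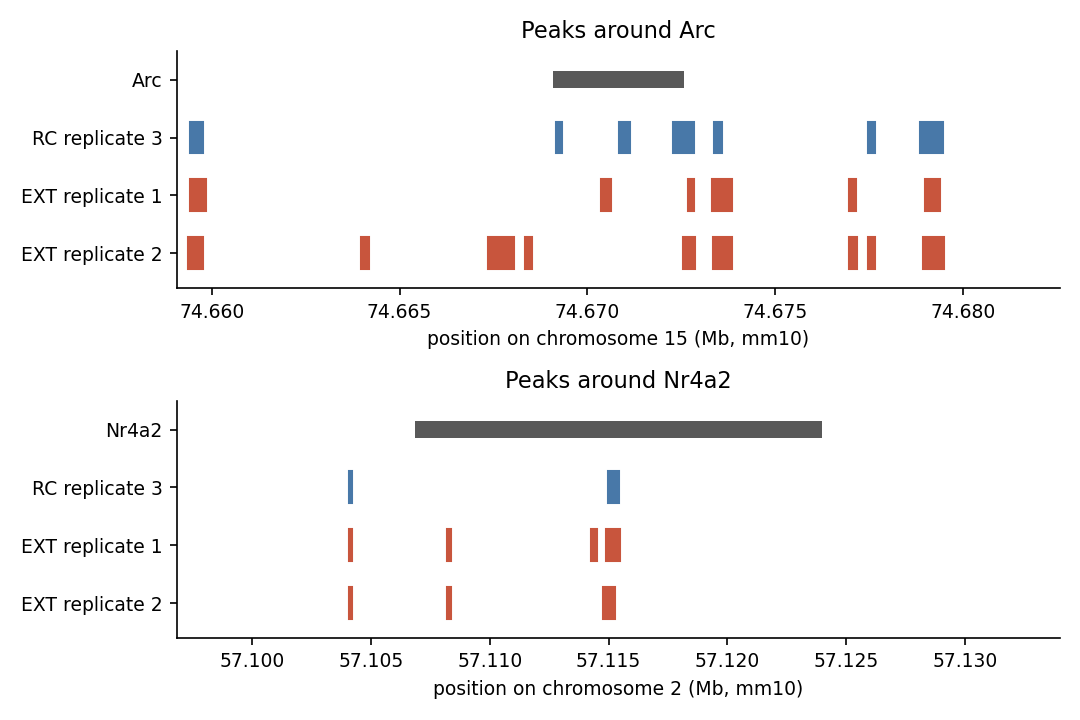
Peaks of the 3 complete lists around Arc on chromosome 15 and Nr4a2 on chromosome 2, with 10 kb either side, position in Mb (mm10). The grey bar is the annotated gene, blue bars are peaks of RC replicate 3 and red bars peaks of the EXT replicates. A peak at the upper end of Arc and a peak inside Nr4a2 appear in all 3 lists.

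The 14-3-3 genes, which encode the family of phosphoprotein-binding adaptors named in the study's title, were accessible in both groups. Their shares stood at the 99.1st, 99.3rd and 90.0th percentile of random lists in RC replicate 3, EXT replicate 1 and EXT replicate 2. Ywhab, Ywhae, Ywhag, Ywhah, Ywhaq and Sfn had an end peak in all 3 complete lists, and Ywhaz in RC replicate 3 and EXT replicate 1. The Ywhab peak stood highest, at the 98.6th, 96.6th and 98.3rd percentile of its lists. For Ywhaz, EXT replicate 2 had a peak within the gene or 1 kb of it but none in the end windows.

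Gene lists for synapses and chromatin were likewise accessible in each complete list. Regulators of histone acetylation stood at the 99.9th, 99.6th and 99.3rd percentile of random lists in RC replicate 3, EXT replicate 1 and EXT replicate 2. Synaptic plasticity genes stood at the 98.9th, 98.4th and 96.1st. Of 25 regulators of histone acetylation, 22, 20 and 21 had an end peak in RC replicate 3, EXT replicate 1 and EXT replicate 2. Hdac1 and Hdac2 had 1 in all 3 lists, and Hdac7 and Hdac9 in none. Of 27 synaptic plasticity genes, 21, 20 and 21 had an end peak, with the NMDA receptor genes Grin1 and Grin2a in all 3 and Gria3 and Dlg4 in none. Named lncRNA genes such as Malat1 and Miat stood out from other lncRNA genes, with 18, 17 and 19 of 24 accessible where random lists gave medians of 33.3%, 29.2% and 37.5%. Meg3 and Snhg14 had no end peak in these lists, though peaks lay within them.

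Pan-neuronal markers had 13, 15 and 17 of 18 genes with an end peak, Syt1 and Snap25 in all 3 lists and Rbfox3, the gene of NeuN, and Celf4 in 1 each. Excitatory neuron markers had 15, 12 and 15 of 18 (99.2nd, 86.5th and 97.6th percentile of random lists). Of these, the vesicular glutamate transporter genes Slc17a7 and Slc17a6 were in all 3, Neurod2 in 1 and Slc30a3 in none. Inhibitory neuron markers had 9, 9 and 10 of 18, close to random lists (30.9th, 39.7th and 31.3rd percentile), with Lhx6 in all 3 and the neuropeptide genes Sst and Vip in none. Oligodendrocyte lineage markers had 3, 4 and 6 of 15, Sox10 and Olig1 in all 3 and Mog in none. Microglia markers had 2, 5 and 4 of 15, Spi1 in all 3 and Cx3cr1 and P2ry12 in none, at the 0.1st, 6.9th and 0.5th percentile of random lists. Endothelial markers had 4, 1 and 4 of 13, with Cldn5 in all 3, Kdr in 2 and Pecam1 and Flt1 in none. Astrocyte markers had 7, 8 and 7 of 14, Gfap and Slc1a2 in all 3 and Aqp4 and Slc1a3 in none. Liver and muscle genes had 11, 8 and 8 of 22, Apoa1 and Apoa2 in all 3 and Apob and Fgb in none. Slc30a3, Mog, Cx3cr1, P2ry12, Flt1 and Slc1a3 had a peak within the gene or 1 kb of it in all 3 lists. Pecam1 had such a peak in 1 list, and Sst, Vip, Aqp4, Apob and Fgb in none. Counted in this way, microglia markers had 7, 9 and 9 of 15 and oligodendrocyte lineage markers 11, 11 and 12. Pan-neuronal markers had 17, 18 and 18 of 18.

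Housekeeping genes had 19, 17 and 18 of 20, Gapdh and Hprt in all 3, Gusb in 1 and Actb in none. Actb had a peak within the gene or 1 kb of it in all 3 lists, so a missing end peak does not mean closed chromatin where the annotated gene reaches past the promoter in use. The lists were not fully separate: Camk2a stood in both the plasticity and the excitatory list, and Homer1 and Bdnf in both the immediate early and the plasticity list. Relative to all genes of its class, 5 of the 14 lists had a higher share in the EXT mean than in RC replicate 3. With a single complete RC list no list was tested between groups.

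**Figure D4:**
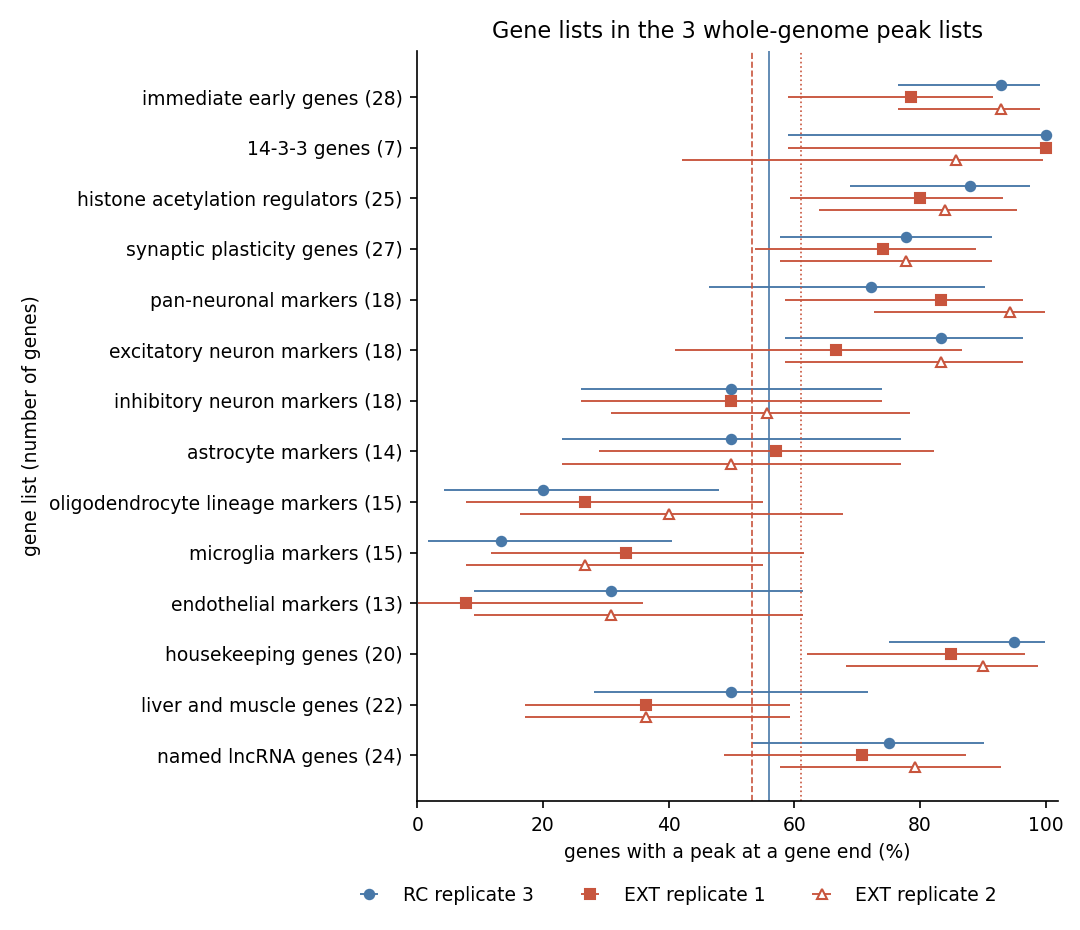
Percent of genes with a peak at a gene end for 14 gene lists in the 3 complete lists, with exact 95% binomial intervals as bars and the share of all protein-coding genes as vertical lines (solid RC replicate 3, dashed EXT replicate 1, dotted EXT replicate 2). Immediate early, 14-3-3 and housekeeping genes lie above these lines, and microglia, oligodendrocyte and endothelial markers below.

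The 3 highest-ranked peaks were the same places in each complete list. No peaks were removed here for lying in regions of unusually high signal, so agreement at these places need not reflect open chromatin. The top peak of all 3 lay on chromosome 2 near positions 98666179 to 98667389, far from any protein-coding gene (Lrrc4c, at 1034507 bp, was nearest), with pileups of 8123, 8781 and 5432 tags. Peaks within Chl1 on chromosome 6 and near Mex3c on chromosome 18 followed in all 3, with Cdk8 in RC replicate 3 and EXT replicate 1, Cmss1 in both EXT lists, Axin2 in RC replicate 3 and Rpp21 in EXT replicate 2. On the part of chromosome 1 in the short lists, the top peaks were nearest to Dsel, Fam174a, Dnpep, Aamp and Tsga10 in RC replicate 1 and to Hs6st1, Eloc, Vcpip1, Ccdc115 and Actr1b in RC replicate 2. Each of these regions overlapped a peak in every list that reached it.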

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

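Settings that used wider extents, whole gene spans, tag-size subsets or the lists as they stand were chosen after the result was seen; the others were planned, but run on parts of the genome and gene-end windows that were set after the files were seen. No difference between the groups passed its test under any setting, and with at most 3 libraries against 2 none could. The log2 difference in peak number, -0.18, ranged from -0.43 without EXT replicate 2 to 0.076 without EXT replicate 1, was 0.105 without the RC replicate 1 and 2 lists, 0.027 over the whole genome, and 3.43 (exact permutation p = 0.3) when the lists were counted as they stand, a value set by where 2 of them end. The share of peaks at gene ends, 1.174 percentage points, ranged from -0.839 without EXT replicate 1 to 3.19 without EXT replicate 2. It was -0.470 without the RC replicate 1 and 2 lists and -0.0169 in the 3 libraries with longer tags. The share within gene spans, another quantity, differed by -3.37 (two-sided exact permutation p = 0.2). Peaks outside genes made up 24.2% to 27.6% in RC and 29.2% to 30.0% in EXT libraries on the shared part. On the longer part of chromosome 1 the groups overlapped, with 26.0% and 26.6% in RC and 26.4% and 28.5% in EXT libraries. For protein-coding genes, -0.743 ranged from -2.55 without RC replicate 3 to 0.849 without EXT replicate 1 and was 0.849 in lists of equal length, 2.87 without the RC replicate 1 and 2 lists, 0.107 on the longer part of chromosome 1, 1.19 over the whole genome, -2.76 with the stricter list, and 1.27 and -2.71 in the 2 libraries with shorter tags on the shared part and over the whole genome. For lncRNA genes, -1.01 ranged from -4.02 without EXT replicate 2 to 2.01 without EXT replicate 1 and was 0.431 in lists of equal length, 3.02 without the RC replicate 1 and 2 lists, 0.718 with 500 bp windows, 1.64 over the whole genome, -3.55 there in the shorter-tag libraries and -3.45 for gene spans. The count of genes in both EXT lists and no RC list, 0, was 0 to 2 with a library left out, 8 without the RC replicate 1 and 2 lists, 8 on the longer part of chromosome 1, 756 over the whole genome with 1 RC list, 3 and 12 in the longer-tag and shorter-tag libraries, and 1207 in the latter over the whole genome; fewer lists and more genes raise it by construction. The difference in Jaccard index, -0.0106, ranged from -0.0588 without RC replicate 1 to 0.0769 without EXT replicate 2, and was -0.0673 without the RC replicate 1 and 2 lists, -0.0848 over the whole genome, 0.00424 in lists of equal length and 0.0138 in the longer-tag libraries. As a share of the shorter list it was 0.460 percentage points for any overlap and 0.145 for 50% reciprocal overlap. The immediate early gene difference, -8.33 percentage points, ranged from -11.6 to -5.09 with an EXT library left out, and was -12.3 with the stricter list, 0.269 with 500 bp windows, -2.56 with 2 kb windows and -2.18 for gene spans. The number of gene lists higher in EXT, 5, lay between 4 and 6. Except where named, the cause of these changes was not tested.

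Replicate numbers 1 and 2 occur in both groups. Deviations from group means over 2145 regions correlated at -0.185 and 0.123, but the 2 EXT deviations are mirror images, so pairing is untested. With the replicate number as a block, the differences were -0.32 for log2 peak number and 1.99 percentage points for peaks at gene ends. They were -2.55 for protein-coding genes, -3.02 for lncRNA genes and 0 genes in EXT alone. RC replicate 3 has no EXT partner and drops out, so these repeat the values without RC replicate 3 and show no effect of pairing. All but the last moved by over 1.5 times, and none has a test. No block was computed for the overlap of peak sets, which has no value per pair, or for immediate early genes, which lie outside the shared part. Windows at 5′ ends alone were not run, all contigs moved nothing, and lists of equal length fix the number of peaks.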

Other observations

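All tests in this part were chosen after the result was seen. Gene families, grouped by symbol, separated widely in each complete list. Olfactory receptor genes, which neurons of the cortex largely keep silent, had an end peak in 3.2%, 2.6% and 3.8% of 1110 genes in RC replicate 3, EXT replicate 1 and EXT replicate 2, and vomeronasal receptor genes in 2.0%, 1.4% and 1.1% of 355. At the other extreme stood proteasome subunit genes with 38, 36 and 38 of 40 and mitochondrial ribosomal protein genes with 94.9%, 91.0% and 94.9% of 78. Glutamate receptor genes had 74.1%, 66.7% and 74.1% of 27, and GABA-A receptor genes 36.8%, 47.4% and 57.9% of 19, with intervals that overlap between libraries. Potassium channel genes had 57.4%, 52.1% and 70.2% of 94, and Zfp zinc finger genes 66.8%, 65.7% and 77.1% of 397. For both families EXT replicate 2 lay above the other libraries, as it did for all protein-coding genes. Part of the accessibility of lncRNA genes lay where they adjoin other genes. Of the 3845 lncRNA genes with a protein-coding gene end within 5 kb, 51.3%, 47.7% and 58.0% had an end peak in RC replicate 3, EXT replicate 1 and EXT replicate 2. Of the 8882 farther away, 23.0%, 19.4% and 29.8% did.

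Peaks of a fixed width made up a large part of every list. The most common widths were 160 bp, with 20.0%, 16.5% and 13.6% of all peaks in RC replicate 3, EXT replicate 1 and EXT replicate 2, and 150 bp, the length to which tags were extended, with 9.5%, 11.2% and 8.5%. Of the peaks up to 170 bp wide, 11.2%, 12.5% and 9.8% touched a gene end, against 23.9%, 26.1% and 20.5% of wider ones. The 3 complete lists held 5502 peaks with identical start and end, 98.8% of them up to 170 bp wide. Their median fold was 8.19, 8.01 and 5.87, against 3.74, 3.58 and 4.27 for the other peaks of each list, so a high fold alone did not mark a broad accessible region.

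Peak sets of RC replicates 1 and 2 and EXT replicate 2 overlapped each other more than those of RC replicate 3 and EXT replicate 1. The split puts both groups on each side, so training as labelled does not account for it. The EXT pair differed by -0.184 (bootstrap SE 0.013, over 1 Mb bins and not over libraries) from the pairs of EXT replicate 2 with RC replicates 1 and 2. Those pairs were picked for their high overlap, so this value restates the split and is no separate test. Neither unequal numbers of peaks nor narrow peaks account for the split by themselves. The mean Jaccard index within less between its sides was 0.161 in lists of equal length. It was 0.147 (bootstrap SE 0.01) with peaks up to 170 bp wide left out and 461 peaks in each list. RC replicate 3 and EXT replicate 1, at 0.327, then no longer stood above the other pairs. Unequal peak widths stay open, since lists of equal length can still cover unequal numbers of bases. Mean widths on the shared part were 315.7, 321.5 and 297.4 bp in RC replicates 1 and 2 and EXT replicate 2. They were 262.7 and 255.3 bp in RC replicate 3 and EXT replicate 1. As a share of the shorter list, overlaps of any length among the libraries with wider peaks were 68.08% to 72.75%, close to the 67.37% of RC replicates 2 and 3. With 50% reciprocal overlap, which also depends on widths, the split stayed clear. The shares were then 59.58% to 63.58% among these libraries and 37.33% to 54.23% for the other pairs. Tag size and an exchange of the labels of RC replicate 3 and EXT replicate 2 cannot be told apart, since both name this same split, which gave 0.153, the highest of 10, where 10 splits allow no share under 0.05; per the file headers the tag size, 125 and 120 bp in these libraries against 133 to 143 bp, also sets the gap joined within a peak. Total tags stay open too. Their difference correlated with the Jaccard index at 0.214 over pairs, place 83 of 120 orders of the libraries. Were total tags the cause, this correlation should be negative, but its place among the orders decides nothing. The labels name no batch.

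Genes with an end peak in both EXT lists and not in RC replicate 3 could be taken for a response to extinction. Where the RC replicate 1 list reached them, 80.0% of 40 genes had an end peak there too, which argues against training for most of the 40, although RC replicate 1 is also a close match of EXT replicate 2. For comparison, it held an end peak for 96.7% of 630 genes in all 3 complete lists and 4.0% of 668 in none. Of 24 genes in RC replicate 3 and neither EXT list, it held 29.2%. How far peaks near the calling threshold that RC replicate 3 missed could explain the set stays open. The −log10 q of the best peak was under 5 for 56.6% of the 756 genes in EXT replicate 1 but for 17.3% in EXT replicate 2, with medians of 4.7 and 9.7. It was under 5 in both lists for 12.3%. The median rank of the best peak was the 29.5th percentile in EXT replicate 1 and the 46.6th in EXT replicate 2. For genes missing from the other EXT list alone these medians were the 65.1st and 63.0th. Of the 8 genes that RC replicate 1 lacked, 1 had an end peak in RC replicate 2. For the other 7, and for the genes outside chromosome 1, an effect of training was not tested.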
